A study of Mus musculus with 4 samples.

How the data were processed

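RNA sequencing was done on 4 mouse libraries that the labels describe as CD4+ T cells taken by flow cytometry from tumours of B16, a pigmented mouse melanoma line. 2 libraries are labelled WT and 2 are labelled Piezo1KO. Libraries are numbered here by the sample number of their titles. The descriptions and the columns of the table number the WT libraries 2 and 3 and the Piezo1KO libraries 1 and 2, so WT 1 and WT 2 here are their 2 and 3. The labels do not say whether the libraries of a group came from separate animals. The p-values of limma therefore measure only the spread between these libraries, which may be technical. Fisher's exact tests, the permutation test and the list tests at a preset correlation take genes as units. Their p-values do not measure that spread. The labels' protocols describe total RNA from a column kit and a SMARTer mRNA library kit, and they do not give a strand setting.

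The deposited table gives 1 FPKM value (fragments scaled to gene length and library size) for each of 54532 genes and 4 libraries, with the gene length in bases. Reads were cleaned with fastp 0.19.7 and counted per gene with featureCounts 1.5.0-p3 on mm10 (GRCm38), per the submitters' processing notes. The aligner, the annotation release and the formula of the FPKM are not given in the sources used here. Of 54409 genes found in the GENCODE reference used here, 53499 had the same coordinates in the deposited table.

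In every library the deposited FPKM multiplied by gene length came in whole multiples of 1 step, for 100% of values above 0 at a tolerance of 0.05 reads. This gave whole reads per gene, with assigned totals of 15645069 and 15892797 in WT 1 and WT 2 and of 15331499 and 13789266 in Piezo1KO 1 and Piezo1KO 2. The library size implied by the step was 1.26 and 1.28 times the assigned total in WT 1 and WT 2, and 0.962 and 0.544 times in Piezo1KO 1 and Piezo1KO 2. The authors' FPKM values were therefore not scaled to the assigned reads, and which factor was used is not given in the sources used here. A gene with 0 reads was given a floor of 3 reads, and intervals of read shares are exact 95% binomial intervals. Both cover counting error only.

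Values were tested as log2(FPKM + 1) with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend), Piezo1KO minus WT, without a block. Genes with a mean FPKM of at least 1 over the 4 libraries were tested, which left 11085 genes. P-values were two-sided and adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. Fold changes on this scale understate the change of genes with low values. A fold against a group at 0 is given as a lower bound, from the means of both groups with the empty group set to the floor of 3 reads per library. No exact test of 2 libraries against 2 can go below p = 0.333, so limma's pooled variance, with 2 residual degrees of freedom and 2.59 prior degrees of freedom, carries the calls.

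The genes named were chosen by a rule set before the data were examined. Piezo1 came first. The 10 genes higher and the 10 lower with the largest fold change followed, among those that passed the test, did not overlap between groups and had a symbol that was not a predicted-gene, Rik or pseudogene name. Each of 38 gene lists then gave up to 4 members with the smallest p, of which those with an unadjusted p of 0.05 or more were left out. Il9, Spi1, Irf4, Foxp3, Ifng and Hif1a were reported whatever their value. 1 gene that this rule names is not reported here. The lists covered T helper programmes, T cell state, calcium and mechanical signalling, metabolism, stress, cell cycle, and markers of the other cells that a tumour holds. Lists with at least 5 tested members, 31 in all, were tested with limma's camera at a preset correlation of 0.01 between genes, two-sided and adjusted over lists. Members were counted over all genes tested and adjusted over the list alone. A member that passed the filter through 1 group alone tends to be higher in that group. This biases the counts, medians and camera tests of lists that hold such members.

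The test was tried on simulated data for the 11085 genes, with WT means in all 4 libraries and the depth of each. Each group had 1 dispersion for all genes, 0.01 for WT, which was the lowest allowed, and 0.0243 for Piezo1KO. Genes that vary more than this were not simulated, and only genes with a WT mean of at least 5 FPKM were changed. The test recovered 52 of 100 genes changed 2-fold and 99 of 100 changed 4-fold, and called 9 unchanged genes. It called 0 genes when none was changed. In the same simulation, camera at the preset correlation called 0 of 100 unchanged lists and gave a list raised 2-fold an adjusted p of 5.02e-38, against 0.558 with an estimated correlation. Genes were simulated as independent of each other, so this shows nothing of lists whose genes vary together.

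Alternatives set before the data were examined were a pseudocount of 0.1, no filter, a mean FPKM of at least 5, no intensity trend, a robust prior, median centring, quantile normalisation, the sample number as a block, leaving out each library, limma-voom on the whole reads, protein-coding genes alone, an unadjusted threshold, and 2 other forms of camera. 3 more were chosen after seeing the data. They rescaled FPKM to all assigned reads, rescaled it to the reads outside mitochondrial genes, and removed each library's trend with gene length by a lowess curve with a span of 0.3. Where a library was left out, the lone library of its group was assumed to vary like the other group. Analyses used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.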

Results

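Expression was measured by RNA sequencing in 4 libraries labelled as CD4+ T cells sorted from B16 melanomas, 2 labelled WT and 2 labelled Piezo1KO. Piezo1 is a cation channel opened by mechanical force. The series addresses its part in the differentiation of Th9 cells, the CD4+ T cells that make interleukin 9. Between 13789266 and 15892797 reads were assigned to genes per library. At least 1 read was found for 19001 and 19639 genes in WT 1 and WT 2, and for 18365 and 16301 genes in Piezo1KO 1 and Piezo1KO 2.

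Melanocyte transcripts were among the most abundant in all 4 libraries, and T cell transcripts were near the floor. Pmel, a protein of the melanosome matrix, had an FPKM of 1960 ± 83.0 (SD, n = 2) in the WT and 2240.2 ± 103 (SD, n = 2) in the Piezo1KO libraries. Tyrp1, a melanin synthesis enzyme, had 1981 ± 13.2 and 1736 ± 210.1 (SD, n = 2 each). Cd4 had an FPKM of 0.0131 and 0.0368 in WT 1 and WT 2, from 1 and 3 reads, and of 0.589 and 0.298 in Piezo1KO 1 and Piezo1KO 2, from 35 and 9 reads. Cd3e, a subunit of the T cell receptor complex, had 1 and 2 reads in WT 1 and WT 2 and 27 and 0 reads in Piezo1KO 1 and Piezo1KO 2.

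The 18 melanocyte genes held 3.12% (95% interval 3.11 to 3.13%) and 3.19% (3.18 to 3.19%) of assigned reads in WT 1 and WT 2. They held 2.56% (2.56 to 2.57%) and 1.40% (1.39 to 1.40%) in Piezo1KO 1 and Piezo1KO 2. The 20 T cell identity genes held 0.00183% (0.00163 to 0.00206%) and 0.00123% (0.00106 to 0.00141%) in WT 1 and WT 2. They held 0.00682% (0.00642 to 0.00725%) and 0.00199% (0.00176 to 0.00224%) in Piezo1KO 1 and Piezo1KO 2. Among protein-coding genes, the melanocyte list had a median percentile of at least 97.8 in every library, and the T cell identity list of at most 52.0.

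**Figure D1:**
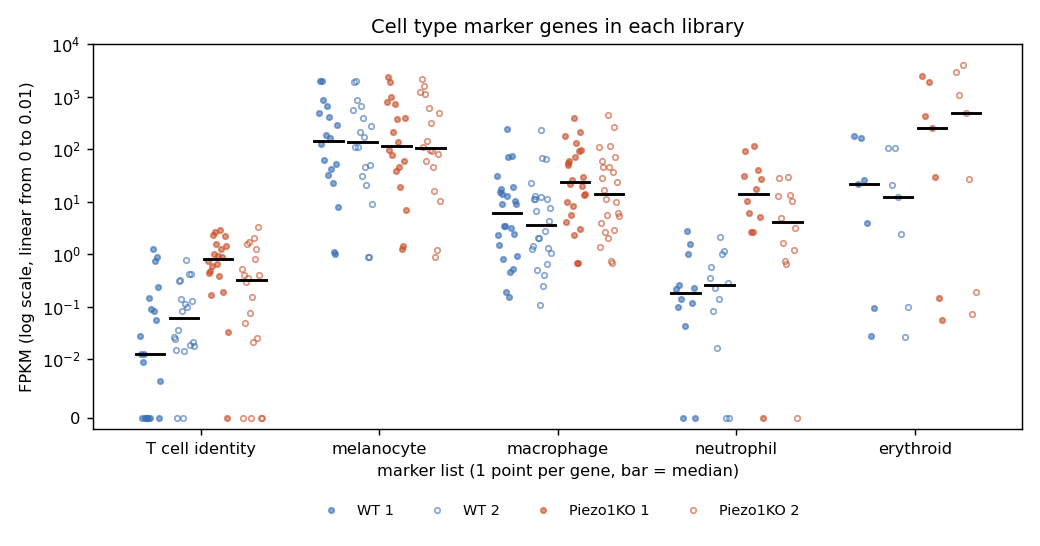
FPKM of each gene of 5 marker lists (1 point per gene, log axis that is linear near 0) in the 4 libraries, with bars at the median. The melanocyte medians lie between 103 and 144, and the T cell identity medians between 0.0125 and 0.815.

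Mitochondrial transcripts also separated the libraries. They took 3.86% (95% interval 3.85 to 3.87%) and 2.99% (2.984 to 3.001%) of assigned reads in WT 1 and WT 2. In Piezo1KO 1 and Piezo1KO 2 they took 20.1% (20.1 to 20.2%) and 48.3% (48.3 to 48.3%). All shares of assigned reads given here count these mitochondrial reads, which lowers the share of every other list, most of all in Piezo1KO 2. A lower share there is therefore no evidence of lower expression among the other genes. Across tested genes the WT libraries correlated at r = 0.988 and the Piezo1KO libraries at r = 0.952, against 0.884 to 0.936 between groups. The median SD of log2 values was 0.075 within WT and 0.21 within Piezo1KO. No pair of libraries of a group held near-identical counts (chi-square per degree of freedom 8.17 for WT and 268 for Piezo1KO, against counting noise alone).

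The first comparison checked the targeted gene. Piezo1 (ENSMUSG00000014444, GRCm38 chromosome 8, 122481698 to 122551329, 9935 bases of gene length) had an FPKM of 27.8 and 27.6 in WT 1 and WT 2, from 5455 and 5578 reads. It had 18.7 and 7.64 in Piezo1KO 1 and Piezo1KO 2, from 2735 and 569 reads, or 67.3% and 27.6% of the WT mean. Means were 27.7 ± 0.179 and 13.2 ± 7.80 (SD, n = 2 each), a log2 fold change of -1.14 with a standard error of 0.41. Both values lay below both WT values, but the difference did not pass the test (limma adjusted p = 0.166, unadjusted p = 0.0431). Without Piezo1KO 1 the log2 fold change was -1.73, and without Piezo1KO 2 it was -0.55. With FPKM scaled to all assigned reads it was -1.87 and passed (limma adjusted p = 5.75e-04), while the median of all genes shifted to -0.67. The labels do not say which part of Piezo1 was removed, and a value over the whole gene does not resolve it.

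**Figure D2:**
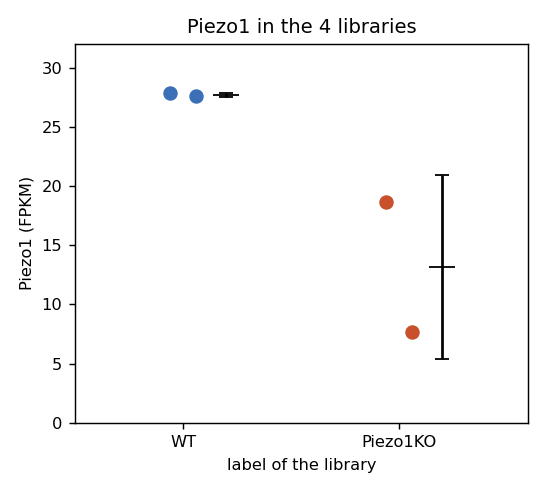
Piezo1 FPKM in each library (points), with the mean and SD of each group of 2 libraries (bars, offset to the right). The WT libraries lie at 27.8 and 27.6, and the Piezo1KO libraries at 18.7 and 7.64.

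The second comparison asked which genes differed between libraries labelled Piezo1KO and WT. The 10 genes with the largest increases under the naming rule were mitochondrial, haemoglobin, S100 and chemokine genes. mt-Co3, mt-Co2 and mt-Atp6, which encode respiratory chain and ATP synthase subunits in the mitochondrial genome, rose by 6.72, 6.54 and 6.26 on the log2 scale (standard errors 0.34, 0.70 and 0.58). S100a9 and S100a8, calcium-binding proteins abundant in neutrophils, rose by 5.30 and 4.04, and the chemokine Ccl3 by 4.77. The haemoglobin genes Hba-a2, Hbb-bs, Hba-a1 and Hbb-bt rose by 4.94, 4.40, 4.31 and 4.22.

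The genes with the largest decreases of log2(FPKM + 1) were mainly small nucleolar RNAs, which guide modification of ribosomal RNA. For those at 0 reads this rank depends on the 1 added to FPKM. Snord55 fell by 3.11, from an FPKM of 25.9 ± 3.26 to 2.13 ± 0.626 (SD, n = 2 each). Snord70, Snord72, Snord110, Snora41, Snord91a, Snora20 and Snora34 had 0 reads in both Piezo1KO libraries, at least 2.65, 2.14, 1.23, 2.31, 1.32, 1.32 and 1.41-fold lower. Malat1, a nuclear long noncoding RNA, fell by 2.65, from 32.1 ± 6.75 to 4.21 ± 0.0471. AC160637.1, a transcript of unsettled class, fell by 3.44, from 19.4 ± 1.44 to 0.929 ± 0.635.

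Of 11085 genes tested, 122 passed, 81 higher and 41 lower in Piezo1KO, with limma adjusted p from 0.0154 for Snord70 to 0.0498 for Snord110 among the 20 named here. The share of calls that were higher, 66.4%, was 14.7% with FPKM scaled to all assigned reads, which shifted the median of all genes to -0.67, and 56.1% with scaling to reads outside mitochondrial genes, which shifted it to -0.20. Without WT 1 or without WT 2, 0 genes passed in limma, with 723 and 616 at an unadjusted p under 0.05. Without Piezo1KO 1 the count was 5859, and without Piezo1KO 2 it was 1579. With the gene length trend removed, 7 genes passed. The groups did not overlap for 3755 genes higher and 3943 lower. Chance gives 16.7% of genes in each direction, and 33.3% in both directions together. The 3755 genes were 33.9% of those tested.

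The gene with the largest absolute change among the 11085, Gm10800, fell outside the naming rule and is given because its value was seen. It had an FPKM of 0.152 ± 0.110 in WT and 213.5 ± 1.95 in Piezo1KO (SD, n = 2 each), a log2 fold change of 7.54 (limma adjusted p = 0.00139). Several gene values are uncertain because reads can be shared. Mitochondrial genes have near-identical nuclear copies, such as Gm28661 and Gm29216, picked here after their values were seen, which rose by 5.35 and 5.58. Haemoglobin genes, Bcl2a1b and Bcl2a1d have close paralogs, Gapdh has many pseudogenes, and small nucleolar RNAs lie inside host genes.

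The Th9 programme showed no call as a list. T cell identity genes took at most 0.00682% of assigned reads in any library. A call or its absence in this and the other T cell lists therefore cannot be assigned to T cells. Il9 had 0 reads in all 4 libraries, where 3 reads would give an FPKM of 0.284 and 0.275 in WT 1 and WT 2 and of 0.380 and 0.747 in Piezo1KO 1 and Piezo1KO 2. Of 16 tested members 0 passed over all genes, and adjusted over the list alone 2 were higher and 1 lower. The list median was -0.13 while the mean was 0.13 (camera adjusted p = 0.699), and the median was 0.078 without Piezo1KO 2. It passed, lower, at a mean FPKM of at least 5 (median -0.26, camera adjusted p = 0.0189). Spi1, which encodes the transcription factor PU.1 of Th9 and myeloid cells, had a log2 fold change of 1.82 (limma adjusted p = 0.0669). Nfatc2, Il10 and Il4ra had -1.13, 1.55 and 1.26 (adjusted p of 0.0805, 0.112 and 0.141). Irf4, a factor needed for Th9 cells, had 13 and 23 reads in WT 1 and WT 2 and 25 and 2 in Piezo1KO 1 and Piezo1KO 2, below the filter.

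Among the other T helper lists, the Th1 list stood higher in Piezo1KO, and its leading members were chemokines that myeloid cells also make. Ccl4, Ccl3 and Ccl5 rose by 3.75, 4.77 and 1.58, while Hlx had 0.96 (limma adjusted p = 0.0955). Of 7 tested Th1 members 3 rose, 6 adjusted over the list alone (median 1.58, camera adjusted p = 8.78e-05, adjusted p = 0.377 with an estimated correlation). The median was 0.34 without a filter, 0.97 with the length trend removed and 1.04 with FPKM scaled to all assigned reads. Ifng, the main Th1 cytokine, had 0 and 1 reads in WT 1 and WT 2 and 1 and 0 in Piezo1KO 1 and Piezo1KO 2. The Treg list had a median of 0.96 over 7 tested members, of which 0 passed over all genes and 4 were higher adjusted over the list alone. Its median was 0.17 with FPKM scaled to all assigned reads, 0.24 without a filter and 0.59 after quantile normalisation. The list took 0.0295% of assigned reads in both WT libraries, and 0.0386% and 0.0197% in Piezo1KO 1 and Piezo1KO 2. Its camera adjusted p was 0.0181, and adjusted p = 0.377 with an estimated correlation; without Piezo1KO 1 the adjusted p was 0.0934. Tnfrsf9, Capg and Entpd1 had 1.62, 0.96 and 1.40 (limma adjusted p of 0.0803, 0.0803 and 0.143). Foxp3, the Treg lineage factor, had 1 and 4 reads in WT 1 and WT 2 and 32 and 6 in Piezo1KO 1 and Piezo1KO 2. The Th2 list (5 tested, 0 passed, 2 higher adjusted over the list alone, median 0.26, camera adjusted p = 0.0582) was led by Areg with 1.38 (limma adjusted p = 0.0741). It passed, higher, after quantile normalisation, among protein-coding genes and with scaling to reads outside mitochondrial genes (camera adjusted p of 0.0274, 0.0438 and 0.0406). It did not pass in voom, with the length trend removed or with an estimated correlation (camera adjusted p of 0.108, 0.173 and 0.377). The Th2 median was 0.0075 without a filter, and leaving out 1 library gave 0.22 to 0.41. The Th17 list (7 tested, 0 passed, 0 adjusted over the list alone, median 0.052) had a camera adjusted p of 0.528. No Tfh gene passed the filter, and the highest Tfh value in any library was 1.25 FPKM, of Bcl6.

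T cell identity genes were at low levels in all 4 libraries. Trbc2 and Trac, the constant regions of the T cell receptor, had FPKM means of 0.0710 ± 0.1004 and 0.158 ± 0.223 in WT and of 2.19 ± 0.644 and 1.95 ± 0.531 in Piezo1KO (SD, n = 2 each). Their log2 fold changes were 1.56 and 1.35, with 1.17 for Thy1 and 0.77 for Lck (limma adjusted p of 0.0809, 0.110, 0.118 and 0.142). These 4 were the tested T cell identity genes, and adjusted over the list alone all 4 were higher. The other 16 of the 20 members were below the filter, and Trbc2, Trac and Thy1 had WT means under 1 FPKM and passed it through the Piezo1KO libraries, so this count is biased towards higher members. Cd8a had 0 reads in WT 1 and WT 2, and 26 and 3 in Piezo1KO 1 and Piezo1KO 2. Gzma, a granule protease of killer lymphocytes, had 0 reads in WT and 3.01 ± 0.507 FPKM in Piezo1KO, at least 20.2-fold higher (limma adjusted p = 0.0391). It was the 1 gene that passed of 6 tested cytotoxic granule genes, with 2 higher adjusted over the list alone (median 1.46, camera adjusted p = 0.00116, adjusted p = 0.377 with an estimated correlation). In WT 1 and WT 2, 1 and 1 of the 18 listed genes reached 1 FPKM. Tested members such as Gzma passed the filter through Piezo1KO alone, which biases these results towards higher members. The median was 2.18 without Piezo1KO 2, 3.40 with a pseudocount of 0.1, 0.66 without a filter, 4.23 in voom and 0.89 with the length trend removed. Srgn and Nkg7 had 3.62 and 1.34 (limma adjusted p of 0.0630 and 0.151). The naive and memory list had a median of -0.074 and a mean of 0.32 over 9 tested genes, 0 passed and 1 higher adjusted over the list alone (camera adjusted p = 0.608). Klf2, Il7r and Tcf7 had 1.48, 0.95 and -0.41 (limma adjusted p of 0.0955, 0.141 and 0.168). The exhaustion list (7 tested, 0 passed, 0 adjusted over the list alone, median 0.038) had a camera adjusted p of 0.608, with Nfil3 at 1.02 (limma adjusted p = 0.122). Without a filter it passed (median 0.24, camera adjusted p = 0.00413).

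Early response genes of T cell receptor and calcium signalling had higher FPKM in Piezo1KO, together with stress genes that the lists share. The early response list's share of all assigned reads, mitochondrial ones included, was not higher in both Piezo1KO libraries. Ier2, an immediate early gene, rose by 1.25 from an FPKM of 18.3 ± 0.405 to 44.9 ± 0.827 (SD, n = 2 each). It was the 1 gene that passed of 20 tested, with 6 higher adjusted over the list alone. The median was 0.50 (camera adjusted p = 0.00235, adjusted p = 0.548 with an estimated correlation), and it was 0.27 without a filter, 0.19 after quantile normalisation and -0.22 with FPKM scaled to all assigned reads. Scaled to reads outside mitochondrial genes, the median was 0.29. Without Piezo1KO 1 the camera adjusted p was 0.120. The list took 0.239% and 0.226% of assigned reads in WT 1 and WT 2, and 0.283% and 0.138% in Piezo1KO 1 and Piezo1KO 2. Egr1, Tnfrsf9 and Ier3 had 1.89, 1.62 and 1.842 (limma adjusted p of 0.0763, 0.0803 and 0.0803). In the stress and dissociation list 1 of 28 genes passed and 16 were higher adjusted over the list alone (median 1.07, camera adjusted p = 1.34e-06, adjusted p = 0.377 with an estimated correlation). With FPKM scaled to all assigned reads that median was 0.31, and after quantile normalisation 0.70. The stress list's share of all assigned reads, mitochondrial ones included, was lower in both Piezo1KO libraries (1.34% and 0.718%) than in WT 1 and WT 2 (1.40% and 1.38%). Atf3 had 1.61 (limma adjusted p = 0.0531). Mitochondrial and haemoglobin transcripts rose in the same libraries.

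Channel and mechanical signalling genes showed no call with the values as deposited. Of 19 tested calcium and mechanosensitive channels, Piezo1 included, 0 passed and 0 passed adjusted over the list alone (median -0.29, camera adjusted p = 0.474). The median was -0.53 without Piezo1KO 1, -0.086 without Piezo1KO 2 and 0.067 at a mean FPKM of at least 5. Trpm7, P2rx7, Trpv2 and P2rx4 had -0.97, -0.53, 0.51 and 0.47 (limma adjusted p of 0.122, 0.130, 0.141 and 0.141), and Trpv2 and P2rx4 turned to -0.25 and -0.25 with FPKM scaled to all assigned reads. The YAP and TAZ list holds targets of a pathway that answers to cell stretch, and also members of that pathway such as Yap1 and Lats1. Its median is therefore no measure of target genes alone. Of its 18 tested genes 0 passed and 1 was lower adjusted over the list alone. Its median was -0.27 (camera adjusted p = 0.0896), and it was -0.13 without Piezo1KO 2 and -0.070 with the length trend removed. Amotl2, Lats1, Ptpn14 and Cyr61 had -1.39, -0.60, -0.79 and 1.04 (limma adjusted p of 0.0913, 0.117, 0.123 and 0.132). In the integrin and actin list 0 of 33 passed and 1 was higher adjusted over the list alone (median 0.25, camera adjusted p = 0.0570), with Coro1a, Fermt3, Itga4 and Arpc3 at 2.48, 1.31, -0.70 and 0.97 (limma adjusted p of 0.0537, 0.106, 0.116 and 0.129). Its median was -0.44 after quantile normalisation and -0.53 with FPKM scaled to all assigned reads. The list passed, higher, in 7 alternatives, with camera adjusted p of 0.00850 without a filter, 0.0489 without WT 2, 0.00101 without Piezo1KO 2, 0.0409 in voom, 0.0335 among protein-coding genes, 0.00426 with the length trend removed and 0.0445 with ranks. The TGF-beta list had 0 of 18 past the threshold and 0 adjusted over the list alone (median -0.27, camera adjusted p = 0.160), with Smurf2 and Ski at -0.51 and -0.98 (limma adjusted p of 0.129 and 0.132). It passed, lower, at a mean FPKM of at least 5 (median -0.27, camera adjusted p = 0.0186). Its median was -0.11 without Piezo1KO 2 and -0.12 with the length trend removed.

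Mitochondrially encoded genes and nuclear oxidative phosphorylation genes had higher FPKM in Piezo1KO. The share of the nuclear ones in all assigned reads, mitochondrial reads included, was not higher in both libraries. All 13 mitochondrially encoded genes had higher values in both Piezo1KO libraries than in either WT library. 4 rose, among them mt-Atp8 by 3.64, and all 13 were higher adjusted over the list alone. The list median was 3.85 (camera adjusted p = 1.36e-09, adjusted p = 0.377 with an estimated correlation). Without Piezo1KO 1 it was 4.71, without Piezo1KO 2 it was 3.17, and after quantile normalisation it was 1.43. Oxidative phosphorylation genes of the nucleus had a median of 0.84 over 65 genes (camera adjusted p = 2.77e-12, adjusted p = 0.548 with an estimated correlation). It was 1.32 without Piezo1KO 1, 0.45 without Piezo1KO 2, 0.41 after quantile normalisation and 0.032 with FPKM scaled to all assigned reads. These genes took 1.16% and 1.18% of assigned reads in WT 1 and WT 2, and 1.17% and 1.03% in Piezo1KO 1 and Piezo1KO 2. Ndufa12, a complex I subunit, rose by 2.15 as the 1 gene that passed, and 1 was higher adjusted over the list alone. Ndufa10, Ndufa11 and Ndufs7 had 0.82, 1.12 and 0.99 (limma adjusted p of 0.120, 0.127 and 0.127).

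In the glycolysis list Gapdh, a core enzyme of the pathway, rose by 3.45 from an FPKM of 21.8 ± 8.75 to 243 ± 58.4 (SD, n = 2 each). It was the 1 gene that passed of 23 and the 1 higher adjusted over the list alone. The list median was 0.55 (camera adjusted p = 5.79e-05, adjusted p = 0.377 with an estimated correlation), but -0.092 after quantile normalisation, where the call was lost (camera adjusted p = 0.448). With FPKM scaled to all assigned reads it was -0.21, and the list still stood above the other genes (camera adjusted p = 0.0409). It took 3.797% and 3.56% of assigned reads in WT 1 and WT 2, and 4.18% and 2.63% in Piezo1KO 1 and Piezo1KO 2. Pfkp, Slc2a1 and Pfkl had 0.58, 0.61 and 0.63 (limma adjusted p of 0.129, 0.132 and 0.138), and turned to -0.21, -0.19 and -0.18 with that scaling. The hypoxia list had 1 of 23 genes past the threshold and 3 higher adjusted over the list alone (median 0.55, camera adjusted p = 1.21e-04, adjusted p = 0.548 with an estimated correlation), and a median of -0.25 with FPKM scaled to all assigned reads. After quantile normalisation its call was lost (median 0.11, camera adjusted p = 0.0929). Its share of assigned reads was 0.487% and 0.426% in WT 1 and WT 2, and 0.445% and 0.288% in Piezo1KO 1 and Piezo1KO 2. Ndrg1, a gene induced by low oxygen, rose by 1.33, and Mxi1 and Selenbp1 had 0.82 and 0.89 (limma adjusted p of 0.0916 and 0.0999). Hif1a itself had an FPKM of 60.5 ± 2.84 and 56.6 ± 1.72 (SD, n = 2 each), with a log2 fold change of -0.094 (limma adjusted p = 0.668). Ribosomal protein genes had a median of 1.44 over 76 genes, of which 0 passed, also adjusted over the list alone (camera adjusted p = 1.00e-13, adjusted p = 0.549 with an estimated correlation). The median was 2.20 without Piezo1KO 1, 0.72 without Piezo1KO 2, 0.63 with FPKM scaled to all assigned reads and 0.41 after quantile normalisation. Rpl28, Rpl24 and Rpl37a had 1.77, 1.67 and 2.504 (limma adjusted p of 0.135, 0.135 and 0.141).

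Interferon response and chemokine genes had higher FPKM in Piezo1KO, as did the myeloid markers. Ifi27l2a, Isg15 and Isg20, which interferons induce, rose by 2.42, 1.43 and 1.67, and Irf7 had 1.33 (limma adjusted p = 0.0841). Of 18 tested interferon genes 3 rose, 7 adjusted over the list alone (median 0.76, camera adjusted p = 6.43e-05, adjusted p = 0.377 with an estimated correlation). The interferon median was 0.18 with FPKM scaled to all assigned reads and 0.50 with the length trend removed. The interferon list took 0.0230% and 0.0189% of assigned reads in WT 1 and WT 2, and 0.0289% and 0.0167% in Piezo1KO 1 and Piezo1KO 2. Ccl9 and Ccl6, chemokines of myeloid cells, rose by 2.63 and 2.74. Of 16 tested chemokine and receptor genes 6 rose, 13 adjusted over the list alone (median 1.67, camera adjusted p = 1.42e-08, adjusted p = 0.377 with an estimated correlation). That median was 0.56 without a filter, 2.68 at a mean FPKM of at least 5, 2.61 in voom and 1.08 with FPKM scaled to all assigned reads.

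Of 36 tested macrophage, neutrophil and erythroid markers, 34 had higher values in both libraries labelled Piezo1KO than in either labelled WT, as did 33.9% of all tested genes. The macrophage and neutrophil lists had median FPKM values of 24.0 and 13.9 in Piezo1KO 1 against 13.9 and 4.03 in Piezo1KO 2, while the erythroid list had 252 and 487. Of 22 tested macrophage and monocyte genes 5 rose, 20 adjusted over the list alone (median 1.66, camera adjusted p = 4.21e-12, adjusted p = 0.377 with an estimated correlation). The complement genes C1qa and C1qb, the lipopolysaccharide receptor Cd14 and the lectin Lgals3 rose by 1.85, 1.96, 3.92 and 1.74. Of 9 tested neutrophil genes 3 rose and 9 were higher adjusted over the list alone (median 3.09, camera adjusted p = 7.88e-07, adjusted p = 0.431 with an estimated correlation), with Clec4d up by 3.02 and Retnlg at 2.81 (limma adjusted p = 0.0537). In WT 1 and WT 2, 3 and 3 of 12 neutrophil genes reached 1 FPKM. Members such as S100a8 and Retnlg passed the filter through Piezo1KO alone, which biases the neutrophil count and camera result towards higher. The macrophage median was 1.07 with FPKM scaled to all assigned reads. By share of all assigned reads, mitochondrial ones included, the macrophage list was not higher in Piezo1KO 2. It took 0.178% and 0.164% in WT 1 and WT 2, and 0.324% and 0.160% in Piezo1KO 1 and Piezo1KO 2. The neutrophil median was 2.35 without Piezo1KO 1, 4.16 without Piezo1KO 2 and 5.37 in voom. Of 11 tested dendritic cell and MHC class II genes, H2-Eb1 rose by 3.41, and 10 were higher adjusted over the list alone (median 1.59, camera adjusted p = 5.64e-07, adjusted p = 0.377 with an estimated correlation). That median was 3.07 with a pseudocount of 0.1, 2.96 at a mean FPKM of at least 5 and 3.33 in voom. H2-Ab1, H2-Aa and Ccl22 had 3.34, 2.94 and 1.59 (limma adjusted p of 0.0681, 0.0756 and 0.0787). All 5 tested erythroid genes rose, Alas2, the first enzyme of haem synthesis in red cells, by 2.84 (list median 4.31, 5 higher adjusted over the list alone, camera adjusted p = 3.31e-06, adjusted p = 0.377 with an estimated correlation). Tyrobp and Fcer1g, signalling adaptors of NK and myeloid cells, rose by 2.79 and 2.95, as 2 of 4 tested NK and innate lymphoid genes.

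Melanocyte genes showed no call as a list. Of 18 tested, 0 passed and 0 passed adjusted over the list alone (median 0.034, camera adjusted p = 0.608). The median was -0.75 with FPKM scaled to all assigned reads and -0.65 after quantile normalisation, where the list passed as lower (camera adjusted p = 0.00687). Mlana, a melanosome protein, and Ptgds, a prostaglandin synthase, had 0.90 and 0.65 (limma adjusted p of 0.167 and 0.162), and Mlana had an FPKM of 485 and 557 in WT 1 and WT 2 and of 788 and 1206 in Piezo1KO 1 and Piezo1KO 2.

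**Figure D3:**
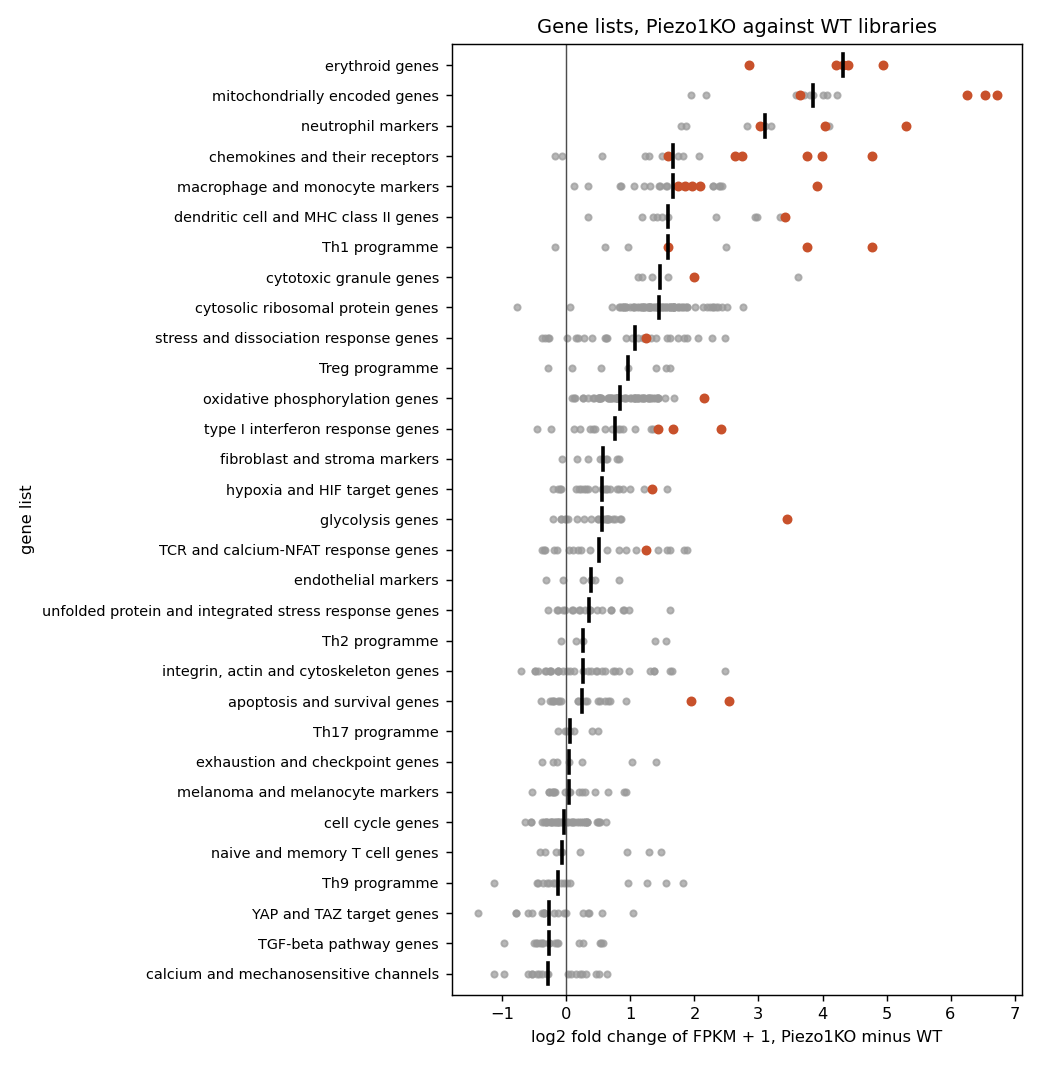
Log2 fold changes of FPKM + 1 (Piezo1KO minus WT) of the tested members of 31 gene lists, with orange points for genes past the limma threshold, grey points for the rest and bars at list medians. Erythroid genes have the highest median (4.31), and calcium and mechanosensitive channels the lowest (-0.29).

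Small nucleolar RNAs made up much of the lower side. Of 67 tested, 22 passed, all lower, and 20 of these 22 had 0 reads in both Piezo1KO libraries (median of the 67, -1.93). They were 22 of the 41 lower calls, more than their share of tested genes (Fisher's exact test, adjusted p = 1.98e-38). This test and the one on pseudogenes take genes as independent. The 20 at 0 reads had no spread within Piezo1KO, which favours a call, and passed the filter through the WT libraries alone. Lower calls of any class numbered 10 in voom on whole reads and 1 with the length trend removed. Unprocessed pseudogenes, among them Gm28661 and Gm29216, made up 7 of the 81 higher calls from 25 tested (Fisher's exact test, adjusted p = 9.97e-09). Of 9940 protein-coding genes tested, 70 passed as higher and 4 as lower.

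Gene length ran with the difference between groups. Across 9927 protein-coding genes outside the mitochondrial genome, which are not independent replicates, the log2 fold change had a Spearman rho of -0.563 with length. It was -0.500 for Piezo1KO 1 and -0.559 for Piezo1KO 2 against the WT mean, and -0.123 for WT 1 against WT 2. The shortest genes, up to 1902 bases, had a median of 0.64, and the longest, from 8919 bases, of -0.35. With this trend removed, the medians of the ribosomal, oxidative phosphorylation, macrophage and erythroid lists were 1.08, 0.52, 1.39 and 3.66. The 7 genes that then passed were mt-Co3, Hba-a2, Ccl9, Gm28661, Gm10222 and Gm10800, higher, and Gm43980, lower; they are named because they were few, after their values were seen.

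**Figure D4:**
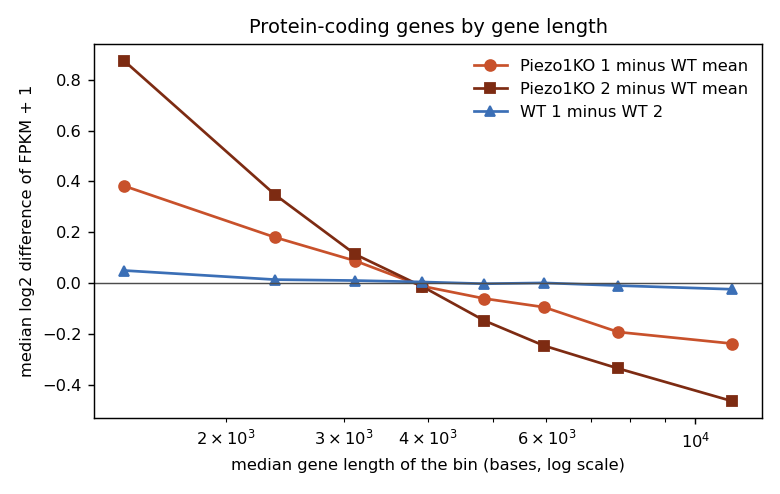
Median log2 difference of FPKM + 1 in 8 bins of protein-coding genes by gene length (log axis, bases), for each Piezo1KO library against the WT mean and for WT 1 against WT 2. In the shortest bin the medians are 0.38 and 0.87 for Piezo1KO 1 and Piezo1KO 2, and 0.050 between the WT libraries.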

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

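The count of 122 calls (81 higher, 41 lower) moved with several choices; the cause was not tested except where fewer genes or libraries entered. Total, higher and lower calls were 1, 1 and 0 without a filter (4156 at an unadjusted p under 0.05), 68, 58 and 10 at a mean FPKM of at least 5, 192, 125 and 67 after quantile normalisation, 1718, 252 and 1466 with scaling to all assigned reads, 7, 6 and 1 with the length trend removed, and 846, 636 and 210 at an unadjusted p under 0.05 with a fold of at least 2. The lower calls were 27 with a pseudocount of 0.1, 10 in voom on whole reads and 17 among protein-coding genes. Leaving out 1 library gave 0 to 5859 calls, 0 to 3046 higher and 0 to 2813 lower. With the length trend removed all 122 kept their sign, and their median absolute log2 fold change went from 2.49 to 2.45 while its standard error went from 0.20 to 0.28 (over all tested genes, from 0.18 to 0.16). The last 3 alternatives named in the methods (both rescalings and the length trend) were chosen after seeing the data.

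With the sample number as a replicate block the counts were 264, 192 and 72, and Piezo1 stayed at -1.14 (limma adjusted p = 0.117). Same-numbered libraries did not deviate together over genes (correlation -0.0329). This rests on 1 difference per group, so it cannot exclude that they share more than a number. These are the numbers of the titles; in the columns of the table the groups share 1 number, which allows no block.

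Piezo1 kept its direction throughout. It passed at -1.87 with scaling to all assigned reads, where 1466 genes passed as lower and the median of all genes was -0.67. Leaving out 1 library gave -1.73 to -0.55. With that scaling Trpv2, P2rx4, Pfkp, Slc2a1, Pfkl, Bcl2l1, Asns, Ptgds and Sparc turned to -0.25, -0.25, -0.21, -0.19, -0.18, -0.14, -0.11, -0.16 and -0.24. The Th9 and melanocyte medians went to -0.86 and -0.75, with camera's direction turned. After quantile normalisation Pfkl, Ptgds and Mlana turned to -0.092, -0.42 and -0.51, and the Th9, integrin, glycolysis and melanocyte lists, in median or in camera's direction, went to -0.20, -0.44, -0.092 and -0.65. With the length trend removed Hif1a turned to 0.071, and the channel list, at -0.032, turned in camera's direction. The Th9 median was 0.0013 without a filter and -0.26, now past the threshold, at a mean of at least 5, where the melanocyte median was 0.0010. Leaving out 1 library gave -0.28 to 0.078 for the Th9 median, -0.12 to 0.36 for the Th17 median, -0.10 to 0.028 for the cell cycle median, -0.13 to 0.14 for exhaustion (-0.060 after quantile normalisation), -0.087 to 0.15 for naive and memory and -0.027 to 0.11 for melanocyte genes. The cause of these turns was not tested. Of the 19 lists called, 14 kept their call without Piezo1KO 1, 16 after quantile normalisation, 17 with scaling to all assigned reads, 18 with the block, 14 at a mean FPKM of at least 5, where 22 lists could be tested, and 0 with an estimated correlation. Of the 4 libraries Piezo1KO 2, with an implied library size of 0.544 times its assigned reads, has the fewest reads and the coarsest values for genes near the floor.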

Other observations

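All tests of explanations below were chosen after the results were seen. Bcl2a1d and Bcl2a1b led the stress and survival genes not yet described. Ddit3 and Trib3, which amino acid or protein folding stress induces, had log2 fold changes of 0.91 and 0.98, and Asns had 0.69 (limma adjusted p of 0.0972, 0.113 and 0.132). Of 21 tested genes of that response 0 passed and 3 were higher adjusted over the list alone (median 0.35, camera adjusted p = 0.00235, adjusted p = 0.377 with an estimated correlation). Without Piezo1KO 1 the camera adjusted p was 0.0653, and the call was also lost with FPKM scaled to all assigned reads (median -0.43, adjusted p = 0.278) and after quantile normalisation (median -0.040, adjusted p = 0.927). The list took 0.607% and 0.616% of assigned reads in WT 1 and WT 2, and 0.534% and 0.316% in Piezo1KO 1 and Piezo1KO 2. Bcl2a1d and Bcl2a1b, survival genes of leukocytes, rose by 2.55 and 1.94 as 2 of 20 tested apoptosis genes, with 4 higher adjusted over the list alone (median 0.24, camera adjusted p = 0.0428, adjusted p = 0.377 with an estimated correlation). Without Piezo1KO 1 that median was 0.10 and the adjusted p 0.187, and after quantile normalisation it was 0.084. The call was also lost at a mean FPKM of at least 5, with the replicate block, with ranks, with scaling to all assigned reads (median -0.39), with scaling to reads outside mitochondrial genes and with the length trend removed, at camera adjusted p of 0.193, 0.0555, 0.0633, 0.0738, 0.0562 and 0.0501. Its share of assigned reads was 0.114% and 0.116% in WT 1 and WT 2, and 0.117% and 0.0652% in Piezo1KO 1 and Piezo1KO 2. Cdkn1a, a cell cycle inhibitor, and Bcl2l1 had 0.93 and 0.60 (limma adjusted p of 0.0899 and 0.118). Of 40 cell cycle genes 0 passed, also adjusted over the list alone (median -0.036, camera adjusted p = 0.699; after quantile normalisation -0.34 and 0.0102), with Cenpf, Kif11 and Bub1b at -0.64, -0.55 and -0.55 (limma adjusted p of 0.123, 0.130 and 0.132).

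Stromal and B cell lists held no gene past the threshold over all genes. Of 9 tested fibroblast genes 0 passed, also adjusted over the list alone (median 0.56, camera adjusted p = 0.0283, adjusted p = 0.570 with an estimated correlation), with Bgn and Sparc at 0.82 and 0.56 (limma adjusted p of 0.132 and 0.145). Without WT 2 or without Piezo1KO 1 the camera adjusted p was 0.118 and 0.521, the medians were 0.31 and 0.22, without a filter the median was 0.29, in voom 0.89, and with FPKM scaled to all assigned reads the median turned to -0.079. The list took 0.0473% and 0.0389% of assigned reads in WT 1 and WT 2, and 0.0534% and 0.0268% in Piezo1KO 1 and Piezo1KO 2. Of 7 tested endothelial genes 0 passed, also adjusted over the list alone (median 0.38, camera adjusted p = 0.386), with Egfl7 at 0.83 (limma adjusted p = 0.159). Igkc, the kappa light chain of antibodies, had an FPKM of 2.57 and 2.68 in WT 1 and WT 2 and of 90.5 and 15.5 in Piezo1KO 1 and Piezo1KO 2 (limma adjusted p = 0.128). Jchain had a log2 fold change of 1.36 (limma adjusted p = 0.141), and 2 of the 4 tested B cell genes were higher adjusted over the list alone. Of the mast cell and basophil list 1 gene was tested, Kit, with a log2 fold change of 0.035. None of the 6 sex-linked genes passed the filter. Xist had 0 reads in 3 libraries and 2 in WT 2, and Ddx3y had 11 and 25 reads in WT 1 and WT 2 and 39 and 27 in Piezo1KO 1 and Piezo1KO 2.

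Melanocyte transcripts were abundant and T cell transcripts scarce in all 4 libraries, although the labels describe CD4+ T cells sorted by flow cytometry, a sort that would remove melanoma cells. CD4+ T cells as the main source of RNA are argued against by the T cell identity list, whose median percentile reached at most 52.0 in any library. Melanoma cells as a source of most of the RNA stay open: the melanocyte list had a median percentile of at least 97.8 in every library, with Pmel near 1960 FPKM in WT, but this value is the pattern itself and no separate test (1 of its 18 genes is also in another list). Whether the table holds other libraries than the labels name cannot be told apart from other origins of the pattern, because the pattern was present in all 4 libraries and no value names its source.

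Blood, myeloid and neutrophil transcripts were higher in the libraries labelled Piezo1KO by FPKM. By share of all assigned reads the macrophage list was not higher in Piezo1KO 2 (0.160%, against 0.178% and 0.164% in WT 1 and WT 2). Mitochondrial reads, at 48.3% of that total in Piezo1KO 2, lower this share. A lower share of melanoma RNA alone would raise neutrophil and endothelial markers alike. The neutrophil median exceeded the endothelial one by 2.71 (exact permutation test over genes, two-sided p = 0.00612). That test cannot decide, because neutrophil genes varied together (estimated correlation 0.974) and some passed the filter through Piezo1KO alone. Unfiltered, neutrophil genes took 0.00128% and 0.00121% of assigned reads in WT 1 and WT 2. They took 0.0464% and 0.00733% in Piezo1KO 1 and Piezo1KO 2. Endothelial genes took 0.0444% and 0.0410% in WT, and 0.0325% and 0.0155% in Piezo1KO. These shares argue against that explanation. The gene length trend as the whole cause is argued against by the macrophage median of 1.39 with the trend removed (quartiles 1.08 and 1.77; 1.66 before). More RNA from myeloid and red blood cells cannot be told apart from induction of these genes: 34 of 36 tested macrophage, neutrophil and erythroid markers were higher in both Piezo1KO libraries, against 33.9% of all tested genes, with Hbb-bs at 2911 and S100a9 at 59.7 FPKM, but these markers are the pattern itself. In WT 1 and WT 2, 18 and 19 of 24 macrophage genes, 3 and 3 of 12 neutrophil genes and 5 and 5 of 7 erythroid genes reached 1 FPKM, 1 macrophage gene is also in another list, and the sort would remove such cells; an effect of genotype stays open and untested.

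Piezo1 was lower in the libraries labelled Piezo1KO. The gene length trend as the whole cause stays open: of 364 protein-coding genes of like length and level 2 changed as far down, but 28 did so in Piezo1KO 1 alone and 1 in Piezo1KO 2 alone. With the trend removed Piezo1 was at -0.83 with a standard error of 0.35 (limma adjusted p = 0.243). The 20 T cell identity genes together had 287 and 195 reads in WT 1 and WT 2. None exceeded 1.28 and 0.789 FPKM there, while Piezo1 had a WT mean of 27.7. These values argue against T cells as the source of most of the drop, unless T cells held far more Piezo1 than these genes. A smaller loss from T cells cannot be told apart from a change in other cells. The drop of 14.6 FPKM was 14.1 times the highest WT mean of a T cell identity gene, but the ratio of Piezo1 to those genes in T cells is not known here, and the labelled genotype stays open.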
